A study of Mus musculus musculus x Mus musculus castaneus with 8 samples.

How the data were processed

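Total RNA, extracted with Trizol and made into strand-marked (dUTP) libraries, was sequenced from 8 samples of female F1 hybrid tail fibroblasts, 2 in each of 4 groups (untreated, 5azadC, VX680, 5azadC+VX680). Per the labels, cells grew for 72 h on 15 cm plates and drugs were added 24 h after plating. Groups were taken from the sample labels. Replicate numbers do not say what a pair of samples with one number shares. Correlations between the replicate differences of any 2 groups lay between -0.0622 and 0.0326. No shared effect of the replicate number on expression was thus seen, and no replicate term entered the tests. Whether samples with one number were handled together cannot be told from this.

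Per the submitters' processing notes, which give no role or order for each tool, the build was mm9 and the tools were TopHat2 2.0.10, HOMER 4.8 and edgeR (no version given). The composite table deposited by the authors holds raw counts per gene, whole numbers that take both alleles together, for 24421 genes. Its length column, per the file headers, gives another quantity, the gene length in bases, and was not used in a test. A second table deposited by the authors holds raw counts assigned to the mus or the cas allele. The deposited normalized composite signal equals the raw composite counts times 1 factor per library (1, 1.537, 1.214, 1.449, 1.132, 1.549, 1.614 and 1.606 in the order untreated, 5azadC, VX680 and combination); how the factors were made is not stated. The deposited tables of allelic differential expression give a per-sample signal that, tested on the values, equals the normalized composite signal of a gene times its mus or cas share in that library. In those tables the authors also give, per the file headers, log2 fold changes and mean log2 CPM, and the p-value and false discovery rate of their test. The 8 columns with mus and cas reads added together were not used, since they repeat the sum. The reference annotation follows another genome build, so no coordinates are given, only chromosomes as the tables list them; 2 genes carry a different chromosome in different tables.

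Total expression was tested on the raw composite counts with edgeR 4.0.16 in R 4.3.3: filterByExpr (12643 genes kept), TMM normalization, 1 mean per group fitted over all 8 libraries, and quasi-likelihood F tests with Benjamini-Hochberg adjusted p under 0.05. There were 6 comparisons: each drug and both against untreated, both against each drug, and the interaction on the log2 scale (both minus 5azadC minus VX680 plus untreated). A positive interaction in a gene that fell means that the combined fall was less than the sum. Likewise, a negative interaction in a gene that rose means that the combined rise was less than the sum. The level with both drugs need not lie below that with either drug. Log CPM used a prior count of 2. For a gene with 0 reads in one group the ratio was computed against 3 counts over the group and written as at least that many fold. For 1 to 3 reads the ratio is given with its 95% counting interval, and fitted fold changes of such genes are not given.

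Allelic ratios were tested by edgeR on the 16 mus and cas columns, with a term per library and a mus-allele term per group, in 10301 genes with a mean of at least 10 allelic reads per library, 278 of them X-linked. The share of mus reads among X-linked reads was pooled over the 277 X-linked genes other than Xist and tested by two-sided exact permutation; shares of single libraries carry exact (Clopper-Pearson) 95% intervals, and a share of 0 carries the limit that 3 counts would give. All 21 gene lists (mitosis and spindle, replication and S phase, p53 targets, germline genes silenced by DNA methylation, interferon-stimulated, imprinted, DNA methylation machinery, X inactivation regulators, escape genes, fibroblast matrix, smooth muscle contractile, secreted inflammatory, cholesterol synthesis, RNA quality, and markers of keratinocytes, leukocytes, endothelium, skeletal muscle, chondrocytes, melanocytes and adipocytes) and all X-linked genes were tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, which tests whether a list moves on balance one way. With an estimated correlation p can rise even where the estimate lies below the preset. A call lost in that setting therefore does not by itself show that the genes of a list were correlated. For 3 lists fewer than 3 genes were measured, so no set test was made: keratinocyte (2 measured), skeletal muscle (2) and melanocyte (2) markers.

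The groups, tests, gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. Named genes are those past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap, the first 6 rises and the first 6 falls of each comparison by log2 fold change; up to 4 members of each list with the smallest p; Xist, Hprt, Pgk1, G6pdx, Aurka, Aurkb, Dnmt1 and Cdkn1a; and, for allelic ratios, X-linked genes changed with both drugs and the escape genes that pass the read filter. For the interaction, no condition on overlap between groups was set. Lamp2, called with a single drug, was named after its values were seen. Some genes that this rule names are not reported here.

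Alternatives covered RLE normalization, DESeq2 1.42.0, no filter (18995 genes), a stricter filter (12418 genes), only the groups compared, limma on log2 of the authors' normalized signal plus 1, a replicate term, adjusted p under 0.01, a change of at least 2-fold, limma-voom, other minimums of allelic reads and each library left out in turn, where the remaining library of a group is assumed to vary like the other groups. For the X-linked share, weighting each gene as in untreated libraries and leaving out Msn were added after the data were seen. Depth was 6908503 to 11169532 total reads and 1804492 to 2983493 allelic reads per library. In counts simulated from a negative binomial with the fitted spread, 36 of 66 genes changed 1.5-fold, 54 of 67 changed 2-fold and 64 of 66 changed 4-fold were called, with 13 false calls among 11723 unchanged genes. A rise of 10 points in the mus share was called in 15.6% of simulated genes with low mus shares and 10 to 99 reads, and in 85% of those with at least 100. Both simulations gave every group the same spread, and the number of changed genes was not matched to the data. In the data 5332 genes changed with 5azadC, and replicates spread unequally between groups. Rates of recovery and of false calls in the data may therefore differ from these.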

Results

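Gene expression was measured by directional sequencing of total RNA from tail fibroblasts of a female F1 hybrid between Mus musculus musculus and Mus musculus castaneus, whose X chromosomes can be told apart by their sequence variants. Cells grew for 72 h on 15 cm plates, with drugs added 24 h after plating. There were 4 groups of 2 libraries each. Untreated cells received the solvent DMSO. The others received 5azadC (5-aza-2'-deoxycytidine, an inhibitor of DNA methylation), VX680 (an inhibitor of Aurora kinases, which act in mitosis), or both drugs together. Per the series title, the study asked whether DNA methylation and Aurora kinase pathways act together in keeping the inactive X chromosome silent.

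The libraries held 11169532 and 7256577 total reads in genes for untreated replicates 1 and 2, and 9189904 and 7698496 for 5azadC. VX680 had 9862392 and 7209664, and the combination 6908503 and 6946619. Between 26.1% and 26.9% of these reads carried a variant that assigned them to the mus or the cas allele. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between these libraries only, which may be technical. Replicates spread by 7.52 (untreated), 20.05 (5azadC), 3.07 (VX680) and 2.76 (combination) times what counting error alone gives, as chi-square per degree of freedom. The 5azadC libraries stood furthest apart, with 700 genes at least 2-fold apart, against 427 between untreated, 249 between VX680 and 380 between combination libraries. Log2 fold changes below are given ± SE from the edgeR fit with 2 libraries per group, and levels as mean CPM (reads scaled to library size) ± SD over those 2 libraries.

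Treatment with 5azadC alone, which asks what the methylation inhibitor did by itself, raised interferon-stimulated genes, germline genes and p53 targets, and lowered fibroblast matrix genes. With an estimated correlation these lists had adjusted p = 0.382, 0.404, 0.0441 and 0.648. Oas3 (chromosome 5), an antiviral oligoadenylate synthetase, went from 0 reads in untreated cells to 25 ± 13.8 CPM, at least 155-fold higher (adjusted p = 1.97e-06). Among the falls were Adamts17 (chromosome 7), a secreted metalloprotease, by -5.09 ± 0.27 in log2 (adjusted p = 2.94e-08), and Hmcn1 (chromosome 1), a basement membrane protein, by -4.26 ± 0.31 (adjusted p = 2.83e-07). In all, 5332 of 12643 genes changed, 2855 up and 2477 down, with 1010 and 731 of them at least 2-fold.

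Other genes with 0 reads in untreated cells also rose with 5azadC. Rps4l, a relative of the X-linked ribosomal protein gene Rps4x, reached 11.5 ± 6.33 CPM, at least 71.0-fold (adjusted p = 5.1e-06). Krt18, a keratin of simple epithelia, reached 5.56 ± 4.75 CPM, at least 35.1-fold (adjusted p = 0.000165). Cd80, a ligand that co-stimulates T cells, reached 4.15 ± 1.22 CPM, at least 25.2-fold (adjusted p = 2.89e-05). St14, an epithelial membrane protease, reached 4.02 ± 1.11 CPM, at least 23.4-fold (adjusted p = 5.73e-05). Falls included the matricellular protein gene Sparcl1 (-4.33 ± 0.22), the fibrillar collagen gene Col11a1 (-4.18 ± 0.23), Sez6l2 (-4.17 ± 0.46) and the kinesin gene Kif26a (-4.10 ± 0.41), with adjusted p between 1.81e-08 for Sparcl1 and 9.52e-06 for Sez6l2. The inhibitor's target Dnmt1 stayed at 694 ± 37.4 CPM against 667 ± 11.4 in untreated cells (log2 change 0.06 ± 0.08, adjusted p = 0.62).

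All 34 measured interferon-stimulated genes rose with 5azadC, as did all 34 when adjusted over the list alone, with a median log2 change of 4.87. Isg15, a ubiquitin-like modifier, rose by 6.22 ± 0.34 (adjusted p = 3e-08), Ifit1 by 4.94 ± 0.28 and the tetherin gene Bst2 by 4.05 ± 0.23. The set test (camera) gave p = 1.86e-19, and adjusted p = 0.382 with an estimated correlation. The 5azadC libraries differed in this group: 33 of the 34 genes were at least 1.5-fold apart between them. Of 14 germline genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone). Tex19.1, which acts in germ cells and placenta, was at least 55.3-fold higher, the transcription factor gene Sohlh2 95.5-fold (interval 26.0 to 795) and the piRNA pathway gene Piwil2 101-fold (17.7 to 4032). The germline median was 6.31, or 4.16 with the 7 genes of 0 reads in 1 group placed at their at-least ratios and the others as fitted. For this list camera p was 2.66e-06, and adjusted p = 0.404 with an estimated correlation.

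Among 29 p53 targets, 25 rose and 1 fell after 5azadC (25 and 1 adjusted over the list alone), with a median of 1.29. Cdkn1a, the cell cycle inhibitor p21, rose from 41.2 ± 1.78 to 284 ± 13.3 CPM (2.78 ± 0.10, adjusted p = 1.7e-09). Ccng1 rose by 2.75 ± 0.12, Plk2 by 2.13 ± 0.12 and Phlda3 by 2.08 ± 0.10. This set kept its call with an estimated correlation (camera p = 3.2e-13, adjusted p = 0.0441 with an estimated correlation). Smooth muscle contractile genes rose in 12 of 14 and fell in 1, the same adjusted over the list alone, with Cnn1 (calponin) up by 3.39 ± 0.17 and Actg2 by 1.81 ± 0.09 (camera p = 1e-05, adjusted p = 0.0729 with an estimated correlation). The estimate for this list was -0.034, below the preset 0.01, so correlated genes do not account for the lost call. Cholesterol synthesis genes rose in 16 of 20 with none falling, both over all genes and adjusted over the list alone, including Cyp51 (0.74 ± 0.09) and Sqle (0.71 ± 0.09). Their camera p was 2.36e-06, and the adjusted p was 0.0729 with an estimated correlation.

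Fibroblast matrix genes moved mostly down with 5azadC: 14 of 27 fell and 4 rose, the same adjusted over the list alone. The collagen cross-linking enzyme Lox fell by 1.74 ± 0.11, Fbln1 by 1.54 ± 0.09 and Pdgfra by 1.90 ± 0.15. The list's camera p was 0.0049, with adjusted p = 0.648 with an estimated correlation, and without 5azadC replicate 1 the list was no longer called and its median went from -0.53 to -0.35. In the DNA methylation machinery 9 of 19 fell and 2 rose (10 and 2 adjusted over the list alone), among them the methylcytosine dioxygenase genes Tet1 (-2.96 ± 0.26) and Tet2 (-1.21 ± 0.14) and the methyltransferase gene Dnmt3a (-0.71 ± 0.09); camera p was 0.0165, and adjusted p = 0.412 with an estimated correlation. Of 18 secreted inflammatory factors, 10 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.127), with the chemokine genes Ccl2 up by 3.01 ± 0.20, Ccl7 up by 2.70 ± 0.23 and Cxcl12 down by -1.79 ± 0.09.

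Of 35 mitosis and spindle genes, 2 rose and 5 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.313), and 3, 10 and 3 fell without untreated replicate 1 and 5azadC replicates 1 and 2. Of 32 replication and S phase genes, 2 rose and 10 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0807). Of these, 3 fell without untreated replicate 1, and 5 without either VX680 or either combination library. Imprinted genes rose in 4 and fell in 7 of 25 (6 and 7 adjusted over the list alone). Markers of other cell types were few: 1 of 3 leukocyte markers rose (Cd68, 1.14 ± 0.26), 2 of 5 endothelial markers rose (Flt1, 1.45 ± 0.14, and Eng, 0.65 ± 0.10), 1 of 4 chondrocyte markers rose (Col2a1, 2.53 ± 0.68), and of 4 adipocyte markers 2 rose and 2 fell (1, 0, 0 and 1 rose without untreated replicates 1 and 2 and 5azadC replicates 1 and 2).

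**Figure D1:**
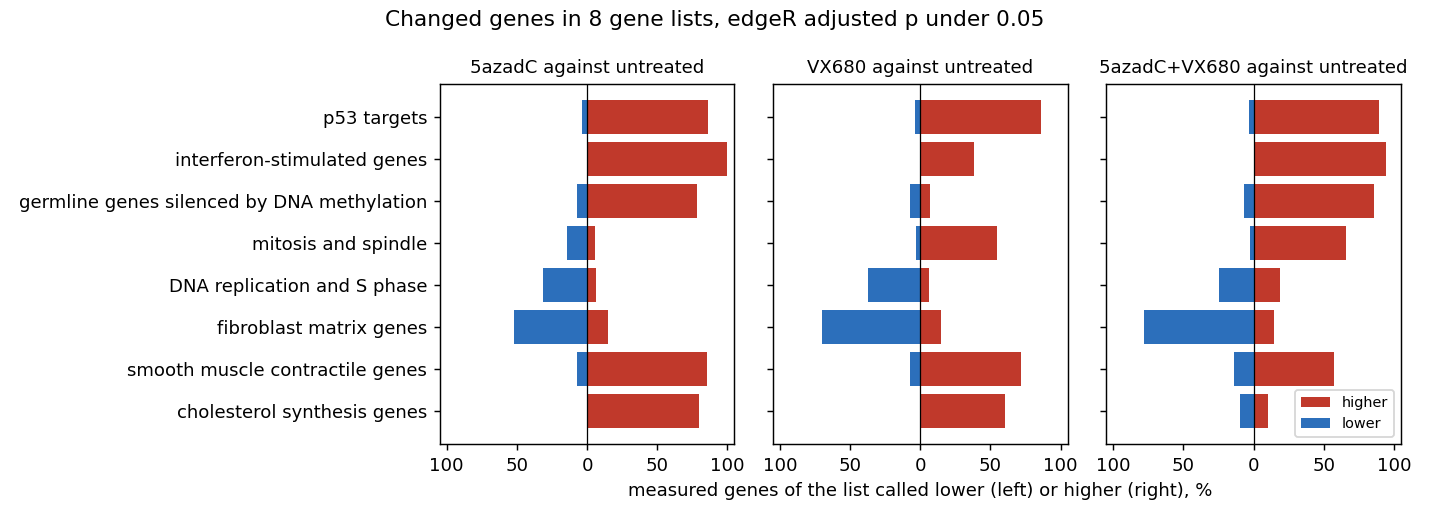
Share of measured genes called lower (to the left) or higher (to the right) by edgeR at adjusted p under 0.05 (x axis, percent). The 8 gene lists are on the y axis, with 1 panel for each of 3 comparisons. All 34 interferon-stimulated genes were higher with 5azadC against untreated.

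Treatment with VX680 alone, which asks what the Aurora kinase inhibitor did by itself, raised p53 targets and mitotic genes and lowered fibroblast matrix genes. With an estimated correlation these lists had adjusted p = 0.0605, 0.554 and 0.535. Tnnt2 (chromosome 1), cardiac troponin T, went from 0 reads to 7.33 ± 3.57 CPM, at least 41.4-fold higher (adjusted p = 1.79e-05). St14 reached 6.56 ± 1.64 CPM, at least 38.0-fold (adjusted p = 1.08e-05), and the mucosal keratin gene Krt13 5.03 ± 1.08 CPM, at least 30.6-fold (adjusted p = 1.23e-05). Hmcn1 fell by 5.59 ± 0.34 in log2 (adjusted p = 3.97e-08) and Ogn (chromosome 13), a small proteoglycan, by 4.91 ± 0.19, from 211 ± 41.4 CPM (adjusted p = 9.88e-10). Of 12643 genes 5834 changed, 3005 up and 2829 down, with 1109 and 826 at least 2-fold. With limma on the authors' signal, where both test and scaling differ, the split was 3646 up and 2144 down. The median change of all genes was then 0.12 here, 0.12 for the combination against untreated and 0.10 for the combination against 5azadC.

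Further rises with VX680 were in Cd80 (at least 18.5-fold, adjusted p = 5.18e-05), Krt18 (at least 9.08-fold, adjusted p = 0.00471) and the protease inhibitor gene Serpinb9b (122-fold, counting interval 33.4 to 1014, adjusted p = 1.24e-07). Krt18 lost its call without untreated replicate 1 (adjusted p = 0.052). Falls were in Adamts17 (-5.40 ± 0.28), the elastic fibre gene Mfap4 (-5.37 ± 0.45), the lipocalin gene Apod (-4.82 ± 0.50) and the transcription factor gene Osr2 (-4.76 ± 0.26), with adjusted p between 1.05e-08 for Adamts17 and 4.85e-06 for Apod. The drug's target gene Aurka rose from 86.1 ± 9.41 to 176 ± 4.16 CPM (1.02 ± 0.10, adjusted p = 3e-06), while Aurkb had 114 against 95.7 CPM (0.25 ± 0.10, adjusted p = 0.066).

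In VX680-treated cells 25 of 29 p53 targets rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 1.21. Cdkn1a reached 349 ± 10.2 CPM (3.08 ± 0.10, adjusted p = 1.5e-10), Ccng1 rose by 2.78 ± 0.12 and Plk2 by 2.39 ± 0.12. Camera gave p = 2.14e-11 for this set, and adjusted p = 0.0605 with an estimated correlation. Of 35 mitosis and spindle genes, 19 rose and 1 fell (19 and 1 adjusted over the list alone), among them the anaphase activator Cdc20 (0.93 ± 0.10), Plk1 (0.76 ± 0.10) and Ube2c (0.67 ± 0.09). Their camera p was 0.000142, with adjusted p = 0.554 with an estimated correlation. Interferon-stimulated genes rose in 13 of 34 (12 adjusted over the list alone) with a median of 1.18, including Isg15 (2.09 ± 0.44) and Bst2 (1.62 ± 0.24); camera p was 0.000342, and adjusted p = 0.554 with an estimated correlation. Without untreated replicate 1 only 6 of them rose.

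Fibroblast matrix genes fell in 19 of 27 and rose in 4 with VX680, the same adjusted over the list alone, with a median of -1.01. Lox fell by 2.77 ± 0.12, Pdgfra by 2.73 ± 0.16 and the collagen genes Col3a1 by 2.66 ± 0.18 and Col6a3 by 1.56 ± 0.10 (camera p = 3.56e-06; adjusted p = 0.535 with an estimated correlation). In the DNA methylation machinery 10 of 19 fell and 1 rose (11 and 1 adjusted over the list alone), with Tet1 down by -2.58 ± 0.25 and Tet2 by -1.71 ± 0.14 (camera p = 0.00394; adjusted p = 0.535 with an estimated correlation); 6 fell without VX680 replicate 2. Smooth muscle genes rose in 10 of 14 and fell in 1, with Cnn1 up by 2.91 ± 0.17 and the myosin kinase gene Mylk down by -2.64 ± 0.15 (camera p = 0.000587; adjusted p = 0.206 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 20 with none falling (13 adjusted over the list alone; camera p = 0.00078; adjusted p = 0.219 with an estimated correlation), and in 6 and 7 without VX680 replicates 1 and 2.

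Replication and S phase genes rose in 2 and fell in 12 of 32 with VX680, the same adjusted over the list alone (camera adjusted p = 0.0856). Without VX680 replicates 1 and 2, 7 and 6 of them fell, and with limma on the authors' signal 3 rose and 7 fell. Of 14 germline genes 1 rose and 1 fell, and none passed when adjusted over the list alone (edgeR). Both of those, Piwil2 (adjusted p = 0.026) and Brdt (adjusted p = 0.012), lost their calls without any 1 of several libraries: without untreated replicate 1 the adjusted p was 0.089 for Piwil2 and 0.12 for Brdt. Imprinted genes rose in 5 and fell in 9 of 25 (7 and 10 adjusted over the list alone), with 3 rising without untreated replicate 1 or 2. Inflammatory factors rose in 8 and fell in 3 of 18, with Cxcl12 down by -4.05 ± 0.10. Of 5 endothelial markers 4 rose, with Flt1 up by 2.84 ± 0.13; 1 rose without untreated replicate 1, and 2 without VX680 replicate 1 or 2. Of 4 chondrocyte markers 2 rose and 1 fell, with Col2a1 up by 4.41 ± 0.56 and Sox9 down by -2.34 ± 0.23. The other rise, Col11a2, lost its call with DESeq2 (adjusted p = 0.094), with a replicate block (0.053), and without untreated replicates 1 and 2 and VX680 replicate 2 (0.19, 0.085 and 0.28), and stood at 0.051 and 0.0504 without combination replicates 1 and 2. Leukocyte markers split, with Cd68 up by 1.46 ± 0.26 and Lyz2 down by -0.96 ± 0.35. Of 4 adipocyte markers 1 rose and 2 fell. The calls for Lyz2 and for Lpl, 1 of those 2, were lost with the authors' signal (adjusted p = 0.096 and 0.11) and without any 1 of the 4 libraries compared (up to 0.24 and 0.16).

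With both drugs against untreated cells, the question was how far the combination changed expression. Tnnt2 reached 12.4 ± 0.755 CPM from 0 reads, at least 73.8-fold (adjusted p = 2.53e-06), and Rps4l 11.6 ± 0.449 CPM, at least 69.2-fold (adjusted p = 2.12e-06). St14 was at least 67.5-fold higher, Krt18 at least 56.4-fold and Krt13 at least 53.04-fold. Hmcn1 fell by 8.60 ± 0.46 in log2, from 521 ± 10.5 to 1.32 CPM (adjusted p = 5.97e-09), the proteoglycan gene Aspn by 6.88 ± 0.35 (adjusted p = 4.24e-09) and Eln (chromosome 5), which encodes elastin, by 6.45 ± 0.80 (adjusted p = 1.35e-05). Adamts17 fell by 6.29 ± 0.32, Megf6 by 6.15 ± 0.40 and Ogn by 5.75 ± 0.21. In total 7040 genes changed, 3586 up and 3454 down, with 1568 and 1336 at least 2-fold.

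Of 29 p53 targets, 26 rose and 1 fell with both drugs (27 and 1 adjusted over the list alone), with a median of 1.497. Cdkn1a reached 403 ± 5.12 CPM (3.29 ± 0.10) and Mdm2, whose protein turns p53 over, rose by 2.24 ± 0.09; camera p was 3.48e-11, and adjusted p = 0.0629 with an estimated correlation. Interferon-stimulated genes rose in 32 of 34 with none falling (32 and 1 adjusted over the list alone). Their median was 2.88, or 2.77 with the 2 genes of 0 reads in 1 group placed at their at-least ratios. Isg15 rose by 4.63 ± 0.36 and Bst2 by 2.81 ± 0.23 (camera p = 6.32e-10; adjusted p = 0.407 with an estimated correlation). Germline genes rose in 12 of 14 and fell in 1 (13 and 1 adjusted over the list alone), with Tex19.1 at least 35.6-fold higher and Sohlh2 40.4-fold (10.7 to 341). The germline median was 6.26, or 3.93 with the 7 genes of 0 reads in 1 group placed at their at-least ratios. For this list camera p was 3.67e-05, and adjusted p = 0.407 with an estimated correlation.

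Mitosis and spindle genes rose in 23 of 35 and fell in 1 with both drugs, the same adjusted over the list alone, with Cdc20 up by 1.04 ± 0.10 and Aurka by 0.93 ± 0.10 (camera p = 0.00022; adjusted p = 0.571 with an estimated correlation). Without combination replicate 2, 15 rose. Fibroblast matrix genes fell in 21 of 27 and rose in 4, with a median of -1.80, including Lox (-3.83 ± 0.13), Col1a2 (-2.61 ± 0.12) and Pdgfrb (-2.08 ± 0.09); camera p was 4.18e-07, and adjusted p = 0.407 with an estimated correlation. Among DNA methylation genes 9 of 19 fell and 1 rose (10 and 1 adjusted over the list alone), with Tet1 down by -3.71 ± 0.28 and Dnmt3a by -1.15 ± 0.09 (camera p = 0.00787; adjusted p = 0.407 with an estimated correlation), and the median of -0.45 became -0.25 without combination replicate 1. Smooth muscle genes rose in 8 and fell in 2 of 14 (camera adjusted p = 0.108), with Cnn1 up by 3.10 ± 0.17 and Mylk down by -3.12 ± 0.16, and cholesterol synthesis genes rose in 2 and fell in 2 of 20.

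Replication genes rose in 6 and fell in 8 of 32 with both drugs (camera p = 0.548), with the reductase gene Rrm2 up by 1.06 ± 0.09; their median was -0.02, and 0.10 with limma on the authors' signal. Imprinted genes rose in 6 and fell in 12 of 25 (7 and 12 adjusted over the list alone; 3, 3 and 2 rose without untreated replicates 1 and 2 and combination replicate 2), with Mest down by -4.75 ± 0.40 and Grb10 by -1.25 ± 0.09. Inflammatory factors rose in 9 and fell in 4 of 18, with Cxcl12 down by -4.70 ± 0.10. Markers of other cell types rose in 2 of 5 endothelial genes, in 1 of 4 chondrocyte genes with 1 falling (2 and 1 adjusted over the list alone), and in 2 of 4 adipocyte genes with 2 falling; 1 of 3 leukocyte markers rose (Cd68, 1.79 ± 0.26) and 1 fell (Lyz2, -1.68 ± 0.38). Of 3 genes that mark RNA quality 1 rose: Rn45s, the ribosomal RNA precursor, by 0.98 ± 0.13 (adjusted p = 3.3e-05). Small nuclear and ribosomal RNA genes took 3.45% and 3.71% of reads in the combination libraries, against 1.65% and 1.74% in untreated and between 1.42% and 2.31% in the single-drug libraries.

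Adding VX680 to 5azadC, a comparison of the combination with 5azadC alone, raised mitotic genes and lowered interferon, cholesterol and matrix genes. With an estimated correlation these lists had adjusted p = 0.448, 0.448, 0.0755 and 0.448. Serpinb9b rose by 4.17 ± 0.31 (adjusted p = 9.91e-07), the GTPase-activating protein gene Arap3 by 3.72 ± 0.56 (adjusted p = 0.000336), Gdf6, a bone morphogenetic protein, by 3.30 ± 0.36 (adjusted p = 2.41e-05), Rgs16 by 2.77 ± 0.42 and Tnnt2 by 2.71 ± 0.44. Ndrg2 went from 0.279 to 2.64 CPM (3.06 ± 0.71, adjusted p = 0.00644), and its change was 7.44 without 5azadC replicate 1. Megf6 fell by 4.99 ± 0.43 (adjusted p = 3.16e-06), Aspn changed by -4.85 ± 0.37 (adjusted p = 1.1e-06) and Hmcn1 by -4.34 ± 0.57 (adjusted p = 0.000113). Apod changed by -4.26 ± 0.61, and by -9.13 without combination replicate 2. The near-identical histone genes Hist2h2aa1 and Hist2h2aa2, which may share reads, were lower in the full data (-5.76 ± 1.36 and -5.76 ± 1.35), but at -0.54 without 5azadC replicate 2 (adjusted p = 0.64 and 0.63), and not called without either combination library, with only the groups compared or with limma on the authors' signal.

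In this comparison 3139 genes changed, 1262 up and 1877 down, with 373 and 452 at least 2-fold, and 1714 and 1598 changed without combination replicates 1 and 2. With only the groups compared in the fit, 2160 genes changed, 851 up and 1309 down. With limma on the authors' signal, which changes test and scaling together, the balance turned, to 1904 up and 1330 down. The turn came with a shift in the median log2 change of all genes, to 0.10 from -0.0041 in the main fit. RLE normalization, with the main test, gave 1343 up and 1766 down. Mitosis and spindle genes rose in 28 of 35 with none falling (31 adjusted over the list alone), including Aurka (0.77 ± 0.10), the midzone gene Prc1 (0.73 ± 0.11) and Cdc20 (0.67 ± 0.09); 14 rose without combination replicate 2. Their camera p was 2.87e-12, and the adjusted p was 0.448 with an estimated correlation. Interferon-stimulated genes fell in 30 of 34 and rose in 1, the same adjusted over the list alone, with a median of -1.70 that became -1.02 without 5azadC replicate 1. Oasl2 fell by 3.09 ± 0.37, the RNA sensor gene Dhx58 by 2.16 ± 0.26 and Ifit1 by 1.87 ± 0.22 (camera p = 4.79e-11; adjusted p = 0.448 with an estimated correlation).

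Cholesterol synthesis genes fell in 19 of 20 when VX680 was added to 5azadC, with Cyp51 at -0.81 ± 0.09, Sqle at -0.76 ± 0.09 and the regulator Srebf2 at -0.72 ± 0.09 (camera p = 1.99e-10; adjusted p = 0.0755 with an estimated correlation), and in 12 without combination replicate 1. Fibroblast matrix genes fell in 17 of 27 and rose in 1 (19 and 2 adjusted over the list alone), with Pdgfrb at -1.95 ± 0.09 and Col6a1 at -1.88 ± 0.10 (camera p = 1.99e-08; adjusted p = 0.448 with an estimated correlation). Smooth muscle genes fell in 7 of 14 (camera p = 0.0062; adjusted p = 0.277 with an estimated correlation), with Mylk at -2.49 ± 0.16, and in 3 and 4 without combination replicates 1 and 2. Imprinted genes fell in 8 of 25 and rose in 1 (9 and 1 adjusted over the list alone; camera p = 0.00255; adjusted p = 0.269 with an estimated correlation), with Mest at -3.72 ± 0.43 and Peg10 at -1.38 ± 0.17; 5 fell without combination replicate 2. Of 29 p53 targets 9 rose and 3 fell (camera adjusted p = 0.0662), with Mdm2 up by 0.93 ± 0.09, and 5 rose without combination replicate 2. Of 14 germline genes 1 rose, none fell, and none passed adjusted over the list alone (edgeR), with a median of -0.17. Of 18 inflammatory factors 4 rose and 3 fell (6 and 4 adjusted over the list alone), and 7 rose without 5azadC replicate 1. Among markers of other cell types Flt1 rose by 1.06 ± 0.12 and Eng fell by 0.74 ± 0.10, Fabp4 rose by 2.56 ± 0.33, Sox9 fell by 1.16 ± 0.22, and Col2a1 rose by 1.83 ± 0.43, a call lost without combination replicate 2 (adjusted p = 0.07). The ribosomal RNA precursor Rn45s rose by 1.01 ± 0.13.

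Adding 5azadC to VX680, a comparison of the combination with VX680 alone, raised interferon and germline genes and lowered matrix and cholesterol genes. With an estimated correlation these lists had adjusted p = 0.334, 0.21, 0.334 and 0.061. The umami taste receptor gene Tas1r1 rose by 4.96 ± 0.57 (adjusted p = 0.000369), the apolipoprotein gene Apob by 4.76 ± 0.43, from 0.708 to 20.3 CPM (adjusted p = 7.82e-05), Rps4l by 4.197 ± 0.50 and the renal dipeptidase gene Dpep1 by 3.80 ± 0.51. Abi3bp, a matrix protein gene, fell by 2.35 ± 0.29, from 47.0 ± 6.18 to 9.26 ± 0.764 CPM (adjusted p = 0.000564), and Aspn by 2.94 ± 0.43 (adjusted p = 0.00164). Other changes did not survive the loss of 1 library: Pgm5 (4.10 ± 0.59, adjusted p = 0.056 without VX680 replicate 1), Lgr5 (-2.80 ± 0.49, adjusted p = 0.072 without VX680 replicate 1, 0.073 and 0.093 without combination replicates 1 and 2), and Sfrp2 (-2.67 ± 0.42, adjusted p = 0.056 and 0.072 without combination replicates 1 and 2). Hmcn1 (-3.02 ± 0.65) and Col25a1 (-2.49 ± 0.56) lost theirs without any 1 of the 4 libraries compared, with adjusted p of up to 0.17 for both.

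In this comparison 822 genes changed, 310 up and 512 down, with 133 and 100 at least 2-fold. The count rested on every library compared, with 99 and 163 genes without VX680 replicates 1 and 2, 118 and 133 without combination replicates 2 and 1, and 1545 without either 5azadC library; 2057 genes changed when only these 4 libraries were fitted. Interferon-stimulated genes rose in 24 of 34 (30 adjusted over the list alone), with Usp18 up by 3.19 ± 0.38, Isg15 by 2.53 ± 0.28 and Ifit1 by 2.23 ± 0.27 (camera p = 1.45e-20; adjusted p = 0.334 with an estimated correlation). Without VX680 replicates 1 and 2 and combination replicates 1 and 2, in that order, 6, 5, 9 and 6 rose. Germline genes rose in 9 of 14 (13 adjusted over the list alone), and Tex19.1 was 35.3-fold higher (11.7 to 175). The germline median was 4.63, or 3.78 with the 5 genes of 0 reads in 1 group placed at their at-least ratios. Their camera p was 6.04e-15, the adjusted p was 0.21 with an estimated correlation, and 2, 3, 4 and 3 rose without the same libraries in turn.

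Fibroblast matrix genes fell in 16 of 27 and rose in 1 when 5azadC was added to VX680 (20 and 2 adjusted over the list alone), with Pdgfrb at -1.10 ± 0.09, Lox at -1.05 ± 0.11 and Col6a1 at -0.96 ± 0.10 (camera p = 2.82e-10; adjusted p = 0.334 with an estimated correlation). Without VX680 replicates 1 and 2 and combination replicates 1 and 2, 6, 9, 8 and 5 fell. Cholesterol synthesis genes fell in 10 of 20 (17 adjusted over the list alone), with Insig1 at -0.76 ± 0.11 and Lss at -0.62 ± 0.10 (camera p = 1.55e-11; adjusted p = 0.061 with an estimated correlation), and in 2, 3, 0 and 4 without those libraries in turn. Of 29 p53 targets 9 rose (12 with 1 falling adjusted over the list alone), with Mdm2 up by 0.56 ± 0.08 and the stress cytokine gene Gdf15 by 2.32 ± 0.39 (camera p = 1.42e-07; adjusted p = 0.0724 with an estimated correlation); 0, 2, 1 and 2 rose without those libraries in turn, and 4 with limma on the authors' signal. Losing VX680 replicate 1 gave adjusted p = 0.057 for Mdm2 and 0.1 for Gdf15 (0.056 without combination replicate 1), and the adjusted p of Insig1 and Lss without combination replicate 1 was 0.057 and 0.062. Of 35 mitosis and spindle genes none was called (edgeR), with Bub1 nearest at 0.37 ± 0.12 (adjusted p = 0.087), 1 of 32 replication genes rose (Rrm2, 0.44 ± 0.09, lost without any 1 of the 4 libraries compared, with adjusted p of up to 0.14; camera p = 0.00445; adjusted p = 0.334 with an estimated correlation), and 2 of 14 smooth muscle genes fell. Rn45s rose by 0.77 ± 0.13 (adjusted p = 0.0045), a call lost without VX680 replicate 1 or either combination library (up to 0.13). Sox9 rose by 1.02 ± 0.25 and Lpl fell by 0.78 ± 0.19 (adjusted p = 0.027 each). Both calls were lost without VX680 replicate 1 or 2 or combination replicate 1 (up to 0.28 and 0.24), and that for Lpl also without combination replicate 2 or either untreated library.

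Whether the drugs acted together was tested as the interaction, the log2 change with both drugs minus the sum of the changes with each. It was called in 1967 of 12643 genes, negative in 1341 and positive in 626. Cdkn1a, which rose with each drug, had an interaction of -2.57 ± 0.13 (adjusted p = 1.9e-07), Ccng1 of -2.33 ± 0.16 and Phlda3 of -1.71 ± 0.13. Cd93, which fell with each drug, had a positive interaction (4.04 ± 0.42, adjusted p = 3.87e-05). Its level was 20.2 CPM untreated, 1.56 with 5azadC, 3.74 with VX680 and 4.803 with both. Enpp2, the phospholipase autotaxin, had 4.28 ± 0.53 (adjusted p = 0.000146), Sparcl1 3.68 ± 0.41 (adjusted p = 5.76e-05) and Kif26a 3.91 ± 0.66 (adjusted p = 0.00149). Adamts17 had 4.19 ± 0.68 (adjusted p = 0.00109), and 3.45 without combination replicate 1 (adjusted p = 0.0668). Fgl2 had 3.57 ± 0.93 (adjusted p = 0.0192), and 7.17 without 5azadC replicate 2; its call was lost with DESeq2 (adjusted p = 0.2) and without untreated replicates 1 and 2, VX680 replicate 1 and combination replicate 1 (0.067, 0.058, 0.091 and 0.17).

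The genes with the most negative interaction had 0 untreated reads, so no size is given for them: Cd80 (adjusted p = 0.00111), St14 (0.00217), Krt13 (0.00517), Oas3 (0.00725), Tnnt2 (0.0172) and Krt18 (0.0482). A gene absent from untreated cells that rises with each drug comes out negative on the log2 scale at almost any level with both. These calls therefore do not show that the drugs held each other back. In St14, for instance, levels were 4.02 CPM with 5azadC, 6.56 with VX680 and 11.3 ± 4.09 with both. Calls were lost for Oas3 without untreated replicate 1 or VX680 replicate 1 (adjusted p = 0.053 and 0.12) and for Tnnt2 without untreated replicates 1 and 2 and combination replicate 2 (adjusted p = 0.11, 0.059 and 0.051). The Krt18 call was lost without any 1 library other than 5azadC replicate 2 (adjusted p from 0.058 without 5azadC replicate 1 to 0.21 without untreated replicate 1). The count of 1967 became 1234 without untreated replicate 1, 922 and 1089 without VX680 replicates 1 and 2, and 1065 and 1038 without combination replicates 1 and 2.

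Of 29 p53 targets 21 had a negative interaction and none a positive one (24 adjusted over the list alone), with a median of -1.15. This set kept its call with an estimated correlation (camera p = 5.14e-14, adjusted p = 0.0217 with an estimated correlation). The p53 targets were mostly not lower with both drugs than with either. Against 5azadC 9 rose and 3 fell (median log2 change 0.15), and against VX680 9 rose and 0 fell (median 0.28). Their combined rise was thus less than the sum. Cholesterol synthesis genes were negative in 17 of 20 (19 adjusted over the list alone), with a median of -0.99 and with Nsdhl at -1.33 ± 0.14 and Sqle at -1.12 ± 0.13 (camera p = 1.45e-13; adjusted p = 0.0217 with an estimated correlation). Smooth muscle genes were negative in 11 of 14 (12 adjusted over the list alone), with a median of -1.06 and Cnn1 at -3.20 ± 0.21 (camera p = 1.64e-08; adjusted p = 0.0245 with an estimated correlation), and in 7 without VX680 replicate 1. Interferon-stimulated genes were negative in 27 of 34 (31 adjusted over the list alone), with a median of -2.82, Isg15 at -3.69 ± 0.49 and Bst2 at -2.87 ± 0.30 (camera p = 4.61e-16; adjusted p = 0.384 with an estimated correlation), and in 17 without VX680 replicate 1. Replication genes were positive in 3 of 32 (2 adjusted over the list alone; camera p = 9.21e-05; adjusted p = 0.241 with an estimated correlation), and in 0 without VX680 replicate 1 or combination replicate 2. Of 27 matrix genes 5 were positive and 10 negative, with 5 negative without untreated replicate 1 or VX680 replicate 1, and 6 without either combination library. Inflammatory factors were negative in 6 of 18 (7 adjusted over the list alone), and in 3 without VX680 replicate 1 or combination replicate 2. Of 14 germline genes none was called (edgeR), with Piwil2 nearest (adjusted p = 0.059).

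Several X-linked genes of interest moved in total expression. Xist, the RNA that coats and silences the inactive X, fell from 783 ± 3.11 CPM to 415 ± 14.4 with 5azadC (-0.92 ± 0.08, adjusted p = 1.7e-06), 367 ± 14.7 with VX680 (-1.09 ± 0.08, adjusted p = 2.5e-07) and 427 ± 2.24 with both (-0.87 ± 0.08, adjusted p = 1e-06). Its interaction was 1.13 ± 0.12 (adjusted p = 3.2e-05), and the combination was not called against 5azadC or VX680 (adjusted p = 0.76 and 0.15). Hprt, a purine salvage enzyme gene, rose from 6.16 ± 1.04 to 19.3 ± 3.19, 19.5 ± 2.34 and 24.1 ± 1.85 CPM in the same order of groups (adjusted p = 4.9e-05, 3.6e-05 and 4.4e-06). G6pdx rose with 5azadC (0.48 ± 0.11, adjusted p = 0.0025) and had adjusted p = 0.019 with VX680, lost without untreated replicates 1 and 2 and VX680 replicate 1 (adjusted p = 0.066, 0.074 and 0.19) and with DESeq2 (0.052). Pgk1 was not called in any group (adjusted p = 0.59, 0.068 and 0.3).

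Of 404 X-linked genes 57 rose and 91 fell with 5azadC (57 and 87 adjusted over the list alone; camera adjusted p = 0.127), 69 rose and 102 fell with VX680 (66 and 102), and 89 rose and 123 fell with both (89 and 121). Of 30 X inactivation regulators 4 rose and 5 fell with 5azadC (3 and 4 adjusted over the list alone), 4 rose and 9 fell with VX680, and 5 rose and 8 fell with both. The falls became 9 with 5azadC without 5azadC replicate 1, 4 with VX680 without VX680 replicate 1, and 5 with both without untreated replicate 1 or combination replicate 1. Eed, a Polycomb gene, rose by 0.57 ± 0.12 with either drug and by 0.71 ± 0.12 with both. Of 14 genes known to escape X inactivation 3 rose and 6 fell with 5azadC (4 and 6 adjusted over the list alone), and 4 rose and 7 fell with VX680 and with both. Without untreated replicate 2 the rises were 0, 0 and 1. Rises also became 0 with 5azadC without 5azadC replicate 1, 2 and 1 with VX680 without VX680 replicates 1 and 2, and 1 with both without combination replicate 2. Falls included the proteoglycan gene Bgn at -2.05 ± 0.12 and the ubiquitin ligase gene Mid1 at -1.62 ± 0.19, each with both drugs.

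The study's central question is whether the silent X-linked alleles were expressed. Over 277 X-linked genes without Xist, mus reads made up 4.01% (exact 95% interval 3.83 to 4.19) and 4.05% (3.82 to 4.28) of allelic reads in the untreated libraries, so nearly all X-linked RNA came from the cas allele. The share was 5.26% (5.04 to 5.50) and 4.89% (4.65 to 5.14) with 5azadC, 4.84% (4.63 to 5.05) and 4.96% (4.72 to 5.21) with VX680, and 5.74% (5.46 to 6.03) and 5.80% (5.52 to 6.08) with both. Autosomal genes had group means between 47.3% and 47.9%, but 46.9% and 48.8% in 5azadC replicates 1 and 2 (SD 1.32 points). The 4 groups differed by an exact permutation test over all partitions of the libraries into pairs (p = 0.0190). The 5azadC-treated libraries lay 0.958 points above the others (two-sided exact permutation p = 0.0571 over 70 assignments) and those with VX680 0.783 points above the others (exact p = 0.143). A comparison of 2 libraries with 2 could not go below p = 0.333 in an exact test.

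Relative to untreated cells, the X mus share was higher by 1.05 points with 5azadC (SD of the difference 0.266), by 0.873 with VX680 (SD 0.0897) and by 1.74 with both drugs (SD 0.0491). The combination lay 0.693 points above 5azadC (SD 0.268) and 0.868 above VX680 (SD 0.0949). With each gene at its untreated weight, these were 0.0607 and 0.361 points. The departure from additivity was -0.181 points (SD 0.283), smaller than its spread, with 0.00674 without 5azadC replicate 1 and -0.869 without the top 5 X-linked genes. Because genes differ in their mus share, part of the rise follows from which genes were expressed: with each gene held at its untreated share, gene totals alone gave group means of 4.02%, 4.42%, 4.56% and 4.99% for untreated, 5azadC, VX680 and both. The excess over these was 0.659 ± 0.277 points with 5azadC, 0.346 ± 0.0732 with VX680 and 0.783 ± 0.104 with both. Intervals cover counting error only, since reads copied in amplification are not independent molecules.

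**Figure D2:**
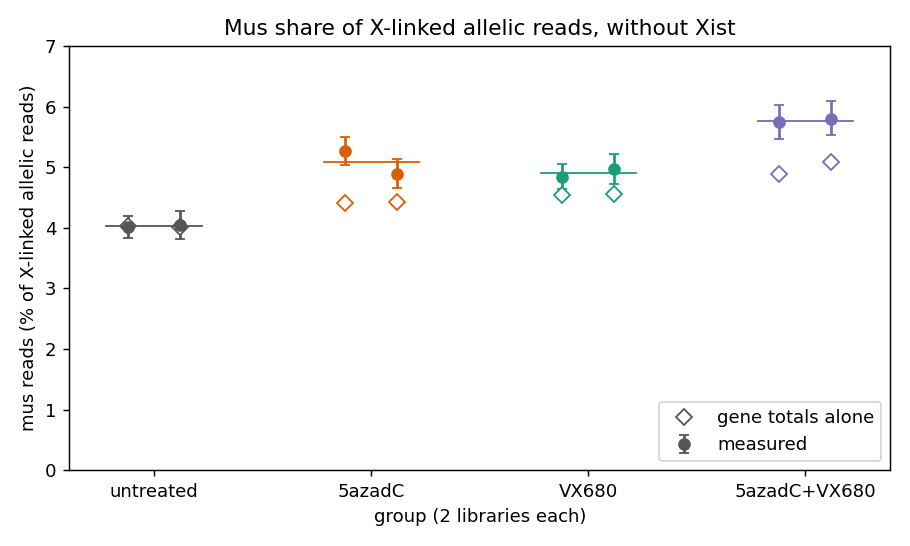
Share of X-linked allelic reads without Xist assigned to mus (y axis, percent) in each library of the 4 groups (x axis); points are libraries with exact 95% binomial intervals, lines are group means and open diamonds are the share that gene totals alone give. Untreated libraries sit at 4.01% and 4.05% and combination libraries at 5.74% and 5.80%.

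Few single X-linked genes changed their allelic ratio. Msn, which encodes the cytoskeletal linker moesin, had 1 mus read of 1023 in untreated cells (0.0978%), 192 of 2880 with 5azadC (6.67%; 8.87% and 3.54% in the libraries), 45 of 4040 with VX680 (1.11%) and 161 of 3778 with both (4.26%). Its log2 mus:cas ratio changed by 5.74 ± 0.59 with 5azadC (adjusted p = 6.73e-09), by 3.18 ± 0.81 with VX680 (adjusted p = 0.0687, and 0.0281 over X-linked genes alone) and by 5.15 ± 0.63 with both (adjusted p = 6e-07), sizes that rest on the single untreated read. The combination was 1.97 ± 0.26 above VX680 (adjusted p = 1.01e-05; not called by DESeq2 or limma-voom, adjusted p = 1 and 0.27) and differed from 5azadC by -0.58 ± 0.22 (adjusted p = 0.666). Total Msn expression rose from 259 to 747, 989 and 1179 CPM, by 1.53 ± 0.10, 1.94 ± 0.10 and 2.19 ± 0.10.

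Mid1, a microtubule-associated ubiquitin ligase gene on the escape list, went from 2.45 ± 0.856% mus reads to 11.97 ± 8.51% with 5azadC (2.25 ± 0.39, adjusted p = 0.000687), 8.27 ± 1.62% with VX680 (1.76 ± 0.42, adjusted p = 0.0341) and 8.89 ± 0.0446% with both (1.90 ± 0.47, adjusted p = 0.0466). Without 5azadC replicate 1 the 5azadC change was 1.28 (adjusted p = 0.49). The VX680 call was lost without any 1 of the libraries compared (adjusted p = 0.1 and 0.38 without untreated replicates 1 and 2, 0.1 and 0.51 without VX680 replicates 1 and 2), and the combination call likewise (0.089 and 0.26 without untreated replicates 1 and 2, 0.26 and 0.17 without combination replicates 1 and 2). DESeq2 called Mid1 with 5azadC (adjusted p = 0.0043) but not with VX680 or both (0.093 and 0.066), and limma-voom called none of the 3 (0.15, 0.41 and 0.36). With at least 30 allelic reads the VX680 and combination calls were lost (0.065 and 0.073). Over both libraries of a group, Mid1 had 31 mus reads of 1210 allelic reads untreated and 74 of 681 with 5azadC. It had 52 of 641 with VX680 and 31 of 349 with both. With both drugs mus reads were thus as many as untreated while allelic reads and total Mid1 expression fell. The higher share there does not by itself show more RNA from the mus allele.

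Bgn, also on the escape list, went from 0.683 ± 0.149% to 2.52 ± 0.576% mus reads with 5azadC (1.94 ± 0.25, adjusted p = 1.38e-06, DESeq2 adjusted p = 1). It had 0.986 ± 0.175% in VX680 and 1.44 ± 1.46% in the combination. Lamp2, a lysosomal membrane protein gene, went from 0.255% to 1.95 ± 0.481% with VX680 (2.97 ± 0.56, adjusted p = 0.00251), a call lost with DESeq2 and limma-voom (adjusted p = 0.88 and 0.28) and without untreated replicate 1 or VX680 replicate 2 (0.16 and 0.11). Xist, expressed from the inactive X, moved the other way, from 91.9 ± 1.79% mus reads to 78.6 ± 1.69% with 5azadC (-1.67 ± 0.19, adjusted p = 5.35e-08), 91.9 ± 1.85% with VX680 and 85.2 ± 4.94% with both (-0.995 ± 0.19, adjusted p = 0.00245). The combination call for Xist was lost without untreated replicate 1 or combination replicate 1 (adjusted p = 0.2 and 0.45, the latter with a change of -0.57) and with limma-voom (0.053). Against VX680 its change was -0.94 ± 0.21 (adjusted p = 0.0341), lost without VX680 replicate 2 or combination replicate 1 (adjusted p = 0.92 and 1), with DESeq2 and limma-voom (1 and 0.67) and with at least 30 allelic reads (0.074).

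**Figure D3:**
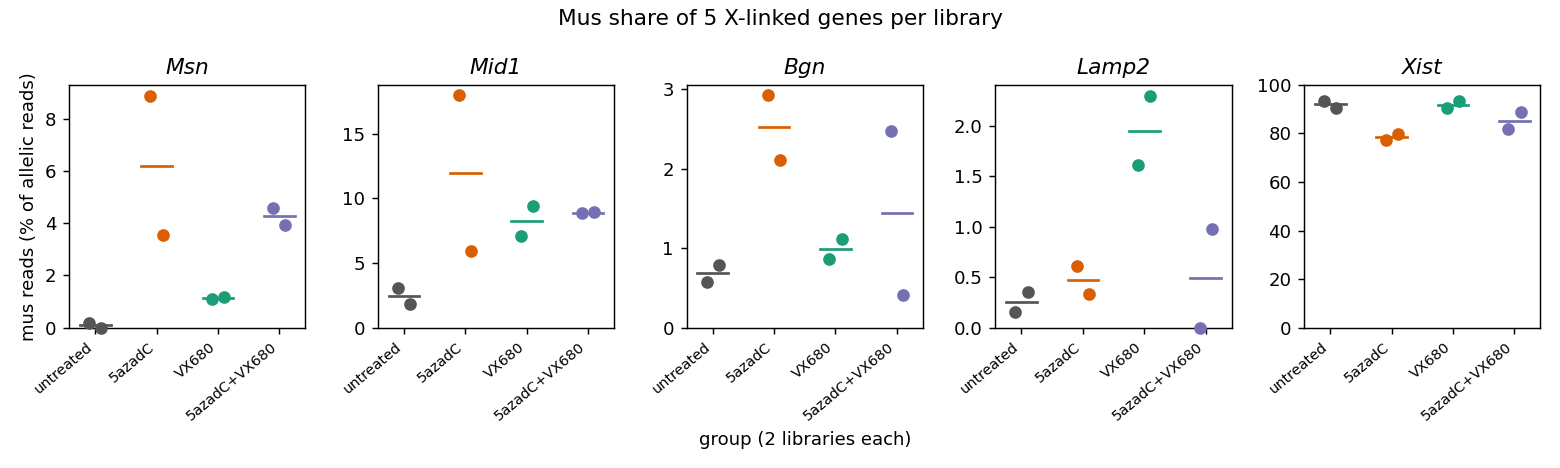
Mus reads as a percentage of allelic reads (y axis) in each library of the 4 groups (x axis) for Msn, Mid1, Bgn, Lamp2 and Xist, 1 panel each; points are libraries and lines are group means. Msn rose from 0.0814% untreated to 6.20% with 5azadC, as means of libraries, and Xist fell from 91.9% to 78.6%.

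Of 278 X-linked genes tested, 4 changed their ratio with 5azadC, 2 with VX680 and 3 with both, all named above, and 2 between the combination and VX680; adjusted over the list alone, the counts were 4, 3, 3 and 2. Without single libraries the 5azadC count ranged from 3 to 4, the VX680 count from 0 (without untreated replicate 1, and without VX680 replicate 2) to 3 and the combination count from 1 (without untreated replicate 1, and without combination replicate 1) to 4. Against 5azadC the combination had 0 calls by edgeR, DESeq2 and limma-voom, with 19 genes at unadjusted p under 0.05 in edgeR. The interaction had 0 calls by the same tools, with 16 at unadjusted p under 0.05 and 1, Msn (-3.76 ± 0.82), adjusted over the list alone (adjusted p = 0.0107). Among 10023 autosomal genes 25, 37 and 50 changed with 5azadC, VX680 and both. The median log2 change over X-linked genes was 0.08, 0.07 and 0.09 in the same order. For X-linked against autosomal genes camera's p was 0.496, 0.756 and 0.181, and that of fry, which asks whether X-linked genes move on balance one way without comparing them with others, was 0.0370, 0.164 and 0.0130 (limma).

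Genes used to read out reactivation had few or no mus reads. Hprt had 0 mus reads of 31 in untreated cells, 2 of 79 with 5azadC, 4 of 101 with VX680 and 0 of 91 with both, and Pgk1 1 of 23, 0 of 25, 0 of 48 and 0 of 25. In simulated genes with low mus shares and 10 to 99 reads, where both lie, 15.6% of rises of 10 points and 46.9% of rises of 20 points were called. G6pdx had mean shares of 2.93%, 4.19%, 8.95 ± 5.84% and 15.6 ± 0.511%, with 2.73 ± 0.78 for the combination (adjusted p = 0.133, and 0.0755 over X-linked genes alone). Among escape genes, Kdm5c had 29.7%, 31.7%, 30.6% and 32.1% mus reads in the 4 groups, Kdm6a 45.6%, 37.0%, 46.2% and 35.7%, Ddx3x 22.04%, 29.4%, 26.4% and 29.2%, and Pbdc1 25.3%, 22.2%, 18.7% and 28.7%, as means of libraries that lay far apart for Kdm6a (SD 31.2 with 5azadC). None of these, nor Eif2s3x, Shroom4, Car5b, 1810030O07Rik, Ftx or Utp14a, was called in the comparisons with untreated.

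Responses were compared between comparisons that share no library. Of 310 genes that rose when 5azadC was added to VX680, 271 also rose with 5azadC against untreated, where independence would give 70, and of 512 that fell 341 did, against 100 (correlation of log2 changes across genes 0.584; genes are not independent replicates). For VX680 the same comparison gave 915 of 1262 shared rises (300 under independence) and 1192 of 1877 shared falls (420).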

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

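Of the tests in this part, the share given by gene totals, the runs without Msn, the run limited to genes with at least 100 untreated reads, the leukocyte and germline comparisons, and both tests of why the 5azadC libraries differ were chosen only after the result was seen.

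The effect of 5azadC differed with and without VX680, by the interaction term, in 1967 genes. The same term had a median of -1.15 over p53 targets, -2.82 over interferon-stimulated genes, -0.99 over cholesterol synthesis genes and -1.06 over smooth muscle contractile genes, each negative. The combination itself had median log2 changes against 5azadC and VX680 of 0.15 and 0.28 over p53 targets. These were -1.70 and 1.72 over interferon-stimulated genes, -0.61 and -0.39 over cholesterol synthesis genes, and -0.31 and -0.06 over smooth muscle genes. The negative term thus did not mean a fall below both drugs in each list. For Msn the interaction in the log2 mus:cas ratio was -3.76, called over X-linked genes alone but not over all genes in the main test, and it rests on 1 mus read in the untreated libraries.

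The mus share of X-linked reads was higher in all 3 drug groups than in untreated cells. A shift in which X-linked genes were expressed gave 55.0% of the rise with both drugs, so it leaves part of the rise, and both combination libraries lay above the share their gene totals give. Msn alone leaves part too, since 62.4% of the remaining rise was still there without it. More reads given to the wrong allele remains open: autosomal genes with under 5% mus reads in untreated cells gained 1.04 points with both drugs against 0.709 for such X-linked genes, or 147% as much. Gains were 2.24 against 0.628 with 5azadC and 2.08 against 0.185 with VX680. Both sets were chosen on the untreated libraries, and part of either gain may follow from that choice. Low-mus autosomal genes may also include alleles silenced by methylation that 5azadC truly raised. Their gain need not measure misassigned reads, so this test cannot decide. With genes of at least 100 untreated reads the figure was 27.8% with both drugs but 226% with 5azadC. With VX680 such autosomal genes gained 1.75 points against 0.132, carried by VX680 replicate 1 (share 4.92%, against 1.83% in replicate 2). So expression from the silent X and misassigned reads cannot be told apart there. The combination points one way and the single drugs the other, and a true autosomal gain would look like misassignment.

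Interferon-stimulated genes were lower in the combination than in 5azadC alone. The strong 5azadC replicate 1 is not the whole cause, since 25 of 34 genes were still lower without it, though the median change shrank from -1.70 to -1.02. Leukocytes in the 5azadC cultures would bring higher leukocyte markers there, but the 3 measured had a median change of 0.51 towards the combination. Cd68, Lyz2 and Cd14 stood at 0.65 ± 0.24, -0.88 ± 0.40 and 0.51 ± 0.37. By edgeR none was called over all genes, and 1 was called higher in the combination over the list alone. A response to 5azadC that shrank in all genes by as much as in these is argued against by the 14 germline genes, with a median of -0.17, from -1.24 ± 0.63 (Dazl) to 2.43 ± 0.76 (Dpep3), and none called lower. A response smaller in part of the genes stays open, since no test of it was made. That VX680 acts on the interferon response itself may be a candidate explanation, and was not tested. With VX680 alone against untreated, 13 of the 34 genes rose and 0 fell by edgeR, with a median log2 change of 1.18. A lowering by VX680 was thus not seen in cells without 5azadC.

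The 5azadC libraries differed more than other replicates. Untreated cells or RNA mixed into replicate 2 would scale all responses alike, but its response was 46.3% of that of replicate 1 for interferon-stimulated genes (quartiles 37.6 to 50.2) and 104.9% for p53 targets (75.4 to 115). Germline genes lay at 37.1% (34.7 to 59.9). Library size is argued against by the untreated libraries, which differ in depth by more and had 3 of 21 interferon-stimulated genes at least 1.5-fold apart, against 33 of 34 between the 5azadC libraries. A difference in culture or in exposure to the drug could produce this pattern and stays open, since the labels do not say what separates the replicates.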

How the results depend on the processing

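Of the alternatives here, weighting each X-linked gene as in untreated cells and leaving out Msn were chosen only after the result was seen. Counts of changed genes kept within 1.5 times under RLE normalization, DESeq2, the stricter filter and the authors' normalized signal in every comparison. Of 11968 alternative results for named genes and lists 11122 were on the same side of the threshold, 642 fell below it and 204 rose past it. With a replicate block 5121, 5695, 6954, 2991, 792 and 1818 genes changed, in the order 5azadC, VX680 and both against untreated, both against 5azadC, both against VX680, and interaction, the order used throughout. Unless said otherwise the cause was not tested. Depth limits the allelic tests: 15.6% of simulated 10-point rises were called in genes with 10 to 99 reads.

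Asking for 2-fold left 1741, 1935, 2904, 825, 233 and 774 genes, and adjusted p under 0.01 left 1745 for both against 5azadC, 299 for both against VX680 and 903 for the interaction, fewer by construction. Both against VX680 had 1299 genes with no filter. With only the groups compared, 4169, 6497, 7284, 2160 and 2057 genes changed in the comparisons other than the interaction. Both against 5azadC and both against VX680, at 3139 and 822 in the main fit, were then nearly equal. The main fit shares 1 estimate of the spread over groups whose replicates spread unequally. Without single libraries the counts ranged from 3948 to 5426, 4129 to 6599, 5646 to 7636, 1598 to 3178, 99 to 1545 and 922 to 2748. Both against VX680 had 99 without VX680 replicate 1 and 1545 without either 5azadC library, and the interaction had 922 without VX680 replicate 1. Set tests called 7, 7, 6, 6, 6 and 5 lists; with an estimated correlation 1, 0, 0, 0, 0 and 3; with fry, which tests another hypothesis, 13, 13, 13, 9, 7 and 8. Leaving out single libraries gave 6 to 8, 7 to 8, 6 to 6, 6 to 7, 5 to 7 and 5 to 7.

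X-linked genes with a changed ratio numbered 4, 2, 3, 0, 2 and 0. For VX680, adjusted p under 0.01 left 1, at least 30 reads 1, and DESeq2 and limma-voom 0; for both against VX680 the same settings left 1, 1, 0 and 0. The interaction had 1 over X-linked genes alone, with at least 5 reads, and with a replicate block. Without single libraries the ranges were 3 to 4, 0 to 3, 1 to 4, 0 to 2, 1 to 3 and 0 to 2.

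For the X-linked mus share, at least 50 reads per gene gave 1.06 points for libraries with 5azadC minus the others (exact p = 0.0286), 0.782 for VX680, 1.82 for both, and 1.04 for both against VX680. Keeping Xist, whose mus reads fell, gave an exact omnibus p of 0.0571 and differences of -1.57, -1.54, -0.293, 1.27, 1.25 and 2.81, reversed in 4. Leaving out escape genes gave 0.715, 0.645 and 1.38 against untreated, 0.733 against VX680, and an interaction of 0.0189, reversed. Leaving out the top 5 genes (Flna, Bgn, Msn, Lamp2, Uba1) gave 1.64, 1.75 and 2.52, 0.773 against VX680, and -0.869 for the interaction. The median share over genes was 0 in every library, so its differences of 0 (exact p = 1) were fixed by that floor and say nothing about the size of the rise. Untreated weights gave 0.510 for 5azadC libraries minus the others (exact p = 0.0286), and 0.659, 0.358, 0.719, 0.0607 and 0.361 for the differences other than the interaction. Without Msn the values were 1.05 for VX680, 1.80 for both and 0.752 against VX680. Libraries with 5azadC minus the others had exact p = 0.0857 without escape genes, and 0.143 without the top 5 genes or without Msn. For libraries with VX680 minus the others, exact p was 0.114 without escape genes and 0.0571 without the top 5 genes or without Msn. It was 0.171 with at least 50 reads, and 0.343 with untreated weights, where the difference was 0.209 points. Single libraries left out gave omnibus p from 0.00952 to 0.0286 (exact), differences of 0.861 to 1.24, 0.813 to 0.934, 1.71 to 1.77, 0.505 to 0.880 and 0.808 to 0.929, and an interaction of -0.368 to 0.00674, reversed without 5azadC replicate 1. Libraries with 5azadC minus the others ranged from 0.807 to 1.14, and with VX680 from 0.602 to 1.02.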

Other observations

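The test of mus reads as counted and the comparison with the authors' allelic tables were chosen only after the result was seen.

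Genes just beyond those named in the report moved with the same drugs. With 5azadC, Ifi44, an interferon-induced gene, was 263-fold higher than in untreated cells (counting interval 46.8 to 10449), Rsad2, an antiviral enzyme gene, 215-fold (38.2 to 8541) and Sncg, which encodes a synuclein, 243-fold (43.1 to 9625), each from 1 untreated read. With both drugs Acsbg1, a fatty acid ligase gene, was 271-fold higher (92.3 to 1318) and F2rl1, a protease-activated receptor gene, 183-fold (32.3 to 7267). Of 2 keratinocyte markers measured, Itga6 rose with 5azadC (0.997 ± 0.198; 0.60 without 5azadC replicate 1), VX680 (1.80 ± 0.19) and both (2.09 ± 0.19), and Krt10 did not pass (-0.07 ± 0.51 with 5azadC). The skeletal muscle marker Acta1 rose with 5azadC (1.05 ± 0.15) and Myh3 was 31.1-fold higher with both drugs (5.09 to 1276). The melanocyte marker Pmel was lower with 5azadC (-1.75 ± 0.51, adjusted p = 0.014; -2.76 without 5azadC replicate 1), a call lost without untreated replicates 1 and 2 and 5azadC replicate 2 (adjusted p = 0.057, 0.052 and 0.074), and Mitf did not pass (0.37 ± 0.20).

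In the authors' deposited tables of the mus allele, 25, 29 and 40 X-linked genes passed their test with 5azadC, VX680 and both, out of 226, 234 and 216 listed, and 15, 18 and 27 of them were higher. Of the higher ones 9, 12 and 16 were not also higher on the cas allele. By the ratio test used here, 2, 1 and 1 of the higher ones were called and 10, 7 and 9 had unadjusted p under 0.05 towards mus. The signal in those tables scales mus shares by composite counts, with a median of 3.31 composite reads per allelic read. Mus reads tested as counted gave 4, 5 and 9 X-linked genes higher out of 277. Over genes in both tables these counts called 1476, 1766 and 2496 against 1259, 2180 and 2806 in the authors' tables.

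Mus shares also varied between libraries on some autosomes, from 62.0% to 76.4% on chromosome 14 and from 48.2% to 55.8% on chromosome 8. On both, the lowest share was in 5azadC replicate 1 and the highest in 5azadC replicate 2.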
